A study of Mus musculus with 4 samples.

How the data were processed

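The data were 4 single-cell RNA-seq libraries of sorted LSK bone marrow cells, 2 from vehicle-treated and 2 from Yoda1-treated wild-type mice, grouped by the treatment label and numbered as the labels number them. The deposited matrices held raw counts of UMIs per gene and cell barcode, not normalized; per the file headers they were written by Cell Ranger 7.1.0, and the values were whole numbers. The submitters' processing notes name Seurat 4.3.0 and the builds GRCm38 and mm10. The labels name both a 10x Genomics library and a microwell chip of another maker, so the capture platform is uncertain. The gene annotation release and the handling of intronic reads were not given in the sources used here. Gene positions were taken from GENCODE M21 (GRCm38), 1-based, through the gene identifiers of the files, of which 52081 of 55357 matched (94.1%). Positions are those of whole genes, since counts are per gene and do not separate exons, introns or UTRs.

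The libraries held 8236, 8709, 9692 and 10168 barcodes (control 1, control 2, Yoda1 1, Yoda1 2). Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrially encoded UMIs; 6.59%, 8.45%, 5.46% and 3.79% of the barcodes exceeded that mitochondrial limit. Scrublet, run per library through scanpy, marked 663, 2, 0 and 0 cells at its automatic threshold, which was taken as not having worked, and no cell was removed as a doublet. As an alternative the 465, 489, 666 and 761 cells with the highest scores were removed, at 0.8% per 1000 cells. Intervals of shares are exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

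Counts were summed per library over all kept cells, or over the cells of a class with at least 50 cells in every library. Genes were filtered with filterByExpr, normalized with TMM and tested with edgeR 4.0.16 (quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05) under R 4.3.3. The SE given with a log2 fold change is its absolute unshrunk value divided by the square root of the quasi-likelihood F statistic. It was not estimated apart from the test, and with 2 libraries per group a change of many SE need not pass. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE normalization, no filter on low counts, a stricter cell filter (at least 1000 genes and at most 5% mitochondrial UMIs), every deposited barcode, doublets removed, the replicate number as a block, and each library left out in turn. In the last of these the lone library of a group was assumed to vary like the group of 2. The interaction between treatment and class was tested with library as a block. Calls of each Yoda1 library alone against the same controls share chance values, so their overlap was set beside that of unchanged libraries simulated at the spread of the controls, taking as many genes of smallest p as the real lists held.

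Clustering used Python 3.11.15, scanpy 1.11.5 and leidenalg 0.10.2: 2000 highly variable genes chosen per library without cell cycle, ribosomal, mitochondrial and sex genes, S and G2/M scores regressed out, 30 principal components, 15 neighbours, Leiden resolution 1.0 and no integration between libraries. A cluster took the name of the marker list with the largest share of its members at least 0.5 (log2) above the other cells and detected in at least 10% of its cells, with at least 3 such members and a pseudocount of 10 CPM. These naming thresholds were set after the data had been seen, and the names rest on marker genes alone. For cycling and distance each cell was thinned to 3000 UMIs, leaving out 226, 252, 154 and 446 shallower cells; distances used 7394 cells per library. Shares, cycling and heterogeneity were compared with an exact two-sided permutation test over the libraries, which has 6 arrangements and a smallest p of 0.333.

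The 36 gene lists, 15 of cell type markers and 21 of processes, were tested with camera on voom values with a preset inter-gene correlation of 0.01, and with an estimated correlation and fry. In the lists 539 of 540 entries matched a gene of the files. Some genes stand in more than 1 list. The lists, the tests, the cell filter, the clustering settings and the rule for named genes were fixed before the data were examined. That rule took, over all cells, genes with adjusted p under 0.05, a mean of at least 10 CPM and groups that do not overlap, leaving out predicted, mitochondrial and ribosomal symbols, or, where none passed, the 5 with the smallest unadjusted p in each direction; the 3 in each direction per class; up to 4 members of each list with the smallest unadjusted p; and Piezo1, Kit, Ly6a, Mki67, Procr, Mpo and Flt3. Members are named for 12 of the 36 lists, a choice made after the results of the lists were seen. Other genes are said to have been chosen after their values were seen. The rule also took 1 member of the HSC list that is not reported here.

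The tests were tried on simulated data with the real genes, library sizes and spread. Over all cells (18182 genes), 40 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2 were recovered, with 14 false calls. In HSC-like cells (14368 genes) 69 of 100 and 100 of 100 were, with 18 false calls. Genes were drawn independently, so a library that differs in many genes together was not simulated. Over all cells 0.0454 of the unchanged simulated genes had an unadjusted p under 0.05, a larger share than the 309 of 18182 real genes. These recovery rates therefore need not hold for the real data. In a single draw, camera with the preset correlation called a simulated list of 20 genes raised 2-fold (adjusted p = 8.34e-35). With the estimated correlation it did not (0.257). The genes were drawn independently of each other, so this cannot show how either setting treats lists whose members move together. In the real lists over all cells the estimated correlation ran from -0.10 for endothelial markers to 0.99 for the interferon list.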

Results

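Single-cell RNA-seq was measured on LSK cells, the lineage-negative, Sca-1-positive, Kit-positive fraction of mouse bone marrow that holds haematopoietic stem cells (HSC) and multipotent progenitors. Wild-type mice had received Yoda1, a small molecule that opens the mechanosensitive cation channel Piezo1, by intraperitoneal injection for 2 weeks, or vehicle. Each group had 2 libraries, called here control 1, control 2, Yoda1 1 and Yoda1 2. After filtering, these held 7620, 7822, 9122 and 9756 cells and 103007020, 89058521, 110493533 and 90577494 UMIs, in that order. The median cell had 11220, 9410.5, 10183.5 and 7311 UMIs and 3503, 3177.5, 3290 and 2782.5 detected genes, so Yoda1 2 was the shallowest library per cell. The labels do not say that the libraries came from separate mice, so p-values measure only the spread between these libraries, which may be technical. Values listed per library below follow the same order.

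The comparison over all LSK cells asked which transcripts differed between Yoda1 and control, with counts summed per library. Such sums also follow the mix of cell classes, which is compared below. Of the genes with a mean of at least 10 CPM, those with the smallest unadjusted p and lower in both Yoda1 libraries under the rule for named genes were genes of granulocytes and mast cells. Pglyrp1, a peptidoglycan-binding protein of neutrophil granules (chromosome 7, 18871331 to 18890459), was at 62.8 ± 3.48 CPM (counts scaled to library size) in control and 37.0 ± 1.30 in Yoda1 (mean ± SD, n = 2 libraries per group). S100a8, a subunit of the neutrophil protein calprotectin (chromosome 3, 90668978 to 90670035), stood at 159, 76.5, 44.5 and 42.7 CPM, with a log2 fold change of -1.43 that was -0.81 without control 1. Of the mast cell and basophil genes, Ms4a2, a chain of the high-affinity IgE receptor, had a log2 fold change of -1.15 ± 0.25 (SE), Cpa3, a carboxypeptidase of mast cell granules, -1.15 ± 0.28, and Hdc, the enzyme that makes histamine, -1.58 ± 0.41. Hdc (chromosome 2, 126593667 to 126619299) was at 50.6, 51.4, 24.6 and 9.45 CPM.

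On the higher side, the same rule named Ccnd1, which encodes the G1 cyclin D1 (chromosome 7, 144929931 to 144939925), at 23.1 ± 3.24 CPM in control and 37.7 ± 6.30 in Yoda1, a log2 fold change of 0.70 ± 0.20. It also named Gbp2, an interferon-induced GTPase (0.63 ± 0.18), Ifi203, an interferon-inducible gene (0.73 ± 0.23), Il18, an inflammatory cytokine (0.90 ± 0.29), and Irf1, a transcription factor induced by interferon (0.51 ± 0.17). Ifi203 was at 180, 184, 358 and 247 CPM and Il18 at 8.93, 12.1, 14.8 and 24.4, where its log2 fold change was 0.50 without Yoda1 2. None of these 10 genes passed the test.

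edgeR's quasi-likelihood test called 0 of 18182 genes at an adjusted p of 0.05, with 148 higher and 161 lower at an unadjusted p under 0.05. Together these are a smaller share than the 0.05 that chance alone gives. They are also a smaller share than the 0.0454 of unchanged genes in the simulated data, so these counts are no sign of change. limma-voom called 0 as well, with 288 at an unadjusted p under 0.05. DESeq2 called 4 genes, all lower: Ngp (log2 fold change -3.21 ± 0.74 in edgeR, DESeq2 adjusted p = 0.0217) and Camp (-2.61 ± 0.62, 0.0217), which encode neutrophil granule proteins, and Mogat2 and Wfdc21 (DESeq2 adjusted p = 0.0217 and 0.0216). Much of the size for Ngp and Camp came from control 1: Ngp was at 2.48, 0.638, 0.125 and 0.211 CPM and Camp at 6.95, 1.85, 0.694 and 0.744, and without control 1 the log2 fold changes were -1.92 and -1.36. Mogat2 and Wfdc21 were named after their values were seen. The count depended on the library left out: edgeR called 0 genes without control 1, 3 without control 2, 938 without Yoda1 1 (496 higher, 442 lower) and 209 without Yoda1 2 (126 higher, 83 lower).

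The 2 Yoda1 libraries differed from the controls in different genes. Among 8370 genes with a mean of at least 10 CPM, 337 differed over 2-fold between Yoda1 1 and Yoda1 2, against 50 between the controls. Yoda1 1 lay nearer the controls, with 69 such genes against control 1 and 110 against control 2. Yoda1 2 lay further off, with 345 and 171. Of 18509 genes tested in both, Yoda1 1 alone against the controls gave 124 higher and 83 lower, and Yoda1 2 alone 484 higher and 442 lower. No higher call was shared, and the lower calls shared 13 genes. Since both comparisons use the same controls, unchanged libraries simulated against them also share genes. Simulated lists of the same sizes, ranked by p, shared 18 to 36 higher and 5 to 14 lower genes in 20 draws (means 25.25 and 10.6). Most genes of those simulated lists did not pass the threshold, unlike the real calls. At the threshold the simulated libraries shared fewer genes than the real lower calls did. Neither comparison is of like lists, so they cannot decide whether the shared lower genes exceed what unchanged libraries give. The simulated libraries gave at most 3 calls at the threshold, so genes were ranked by p instead, a choice made after the data were seen. The 13 genes, listed after their values were seen, were Hdc, Prg2, Prg3, S100a8, S100a9, Clec4a2, Mogat2, Cebpe, Rnase12, Camp, Ngp, Wfdc21 and Ms4a2.

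Marker lists of neutrophils, mast cells and basophils, and eosinophils had medians below both controls in both Yoda1 libraries, as did the MkE, myeloid, megakaryocyte, endothelial, stromal, myelopoiesis, mechanosensitive channel and p53 target lists. In the neutrophil list 6 of 7 measured members were lower, 5 of them with both Yoda1 libraries below both controls. Chance gives 16.7% per direction for a single gene, but members of a list can move together, so such counts are no test. The list medians were 0.43, -0.62, -1.18 and -1.08 (log2 of CPM + 1 against the control mean). Adjusted over the list alone, 4 neutrophil members fell (Ngp, S100a8, Camp, S100a9), as did 3 mast cell and basophil members (Ms4a2, Cpa3, Hdc) and 1 eosinophil member, Prg3, an eosinophil granule protein (-1.83 ± 0.45). Adjusted over the list alone no member of any other list passed, and over all genes none did. All 8 mast cell and basophil members were lower, with medians of -0.19, 0.17, -0.89 and -0.55. Fcer1a, the alpha chain of the IgE receptor, had a log2 fold change of -0.85 ± 0.38, and of -0.42 without control 2. All 5 eosinophil members were lower, with Prg2, the major basic protein, at 80.5, 92.7, 46.7 and 5.89 CPM; Ear6 and Ear1 lay under 0.3 CPM in every library.

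Stem cell genes were high and committed-lineage genes low in Yoda1 2 in particular. That library also had the largest share of HSC-like cells and the smallest shares of MkE- and myeloid-like cells (below). In the HSC list 10 of 12 members were higher, with medians of -0.15, 0.14, 0.09 and 1.01. Hlf, a transcription factor of stem cells, was at 62.1, 76.7, 76.6 and 248 CPM, Procr, the endothelial protein C receptor, at 5.41, 6.78, 7.07 and 29.6, and Mecom, a stem cell transcription factor, at 12.4, 17.5, 17.7 and 50.3. The megakaryocyte-erythroid (MkE) list had 11 of 12 members lower, with medians of 0.16, -0.17, -0.31 and -1.58, among them Gfi1b, a transcriptional repressor of that lineage (-0.92 ± 0.33), Itga2b, the platelet integrin (-0.64 ± 0.25), the membrane transporter Mfsd2b (-1.08 ± 0.49), and the water channel Aqp1 (-1.16 ± 0.60). Most of this came from Yoda1 2, and without it the log2 fold changes of Gfi1b, Itga2b, Mfsd2b and Aqp1 were -0.49, -0.32, -0.46 and -0.49. The myeloid list had 11 of 12 members lower, with medians of 0.05, -0.05, -0.28 and -2.01. Its named members were Cebpa and Cebpe, transcription factors of granulocyte development (-0.76 ± 0.22 and -1.59 ± 0.47), Fcgr3, an Fc receptor (-1.08 ± 0.42), and Elane, neutrophil elastase, at 2538, 2392, 1696 and 468 CPM. Without Yoda1 2 the log2 fold changes of Cebpe and Fcgr3 were -0.98 and -0.52.

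Interferon response genes were high in Yoda1 1. All 20 members lay above both controls in Yoda1 1, while in Yoda1 2 3 lay above both and 16 below both, with medians of 0.12, -0.14, 1.25 and -0.45. Ifit3, an interferon-induced antiviral gene, was at 3.68, 4.43, 32.0 and 4.27 CPM and Iigp1, an interferon-inducible GTPase, at 21.3, 20.2, 86.5 and 21.4. Antigen-presentation genes were low in the same library: the MHC class II list, with 7 of 7 members lower, had medians of -0.12, 0.11, -1.21 and -0.08, and Cd74, the class II invariant chain, was at 203, 246, 50.01 and 213 CPM, H2-Aa at 82.5, 92.7, 20.5 and 77.5, H2-Ab1 at 104, 122, 48.3 and 106, and H2-DMb1 at 40.8, 42.3, 34.4 and 36.2. Within HSC-like cells the MHC class II medians were 0.10, -0.10, 0.13 and -0.29, so the list was not low there in Yoda1 1, and dendritic-like cells, which carry these genes, made up 1.601%, 1.73%, 0.417% and 1.20% of the libraries. B cell markers followed the replicate number more than the treatment, with medians of -1.44, 0.71, -2.79 and 0.34. Ebf1, a B cell transcription factor, was at 5.17, 39.0, 1.43 and 27.3 CPM. The log2 fold changes of Pax5, Vpreb3 and Vpreb1 were -0.73 ± 1.26, -0.74 ± 1.58 and -0.44 ± 0.98. Over all tested genes, too, the log2 difference between control 1 and control 2 correlated at 0.45 with that between Yoda1 1 and Yoda1 2. The crossed numbering gives -0.45 by construction, so the value cannot show that the numbers pair the libraries. With the replicate number as a block, edgeR called 0 genes, with 1367 rather than 309 at an unadjusted p under 0.05.

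Immediate early genes, which cells switch on within minutes of a stimulus, were lower in 15 of 16 members, with medians of -0.34, 0.28, -0.74 and -0.06. Fos, a subunit of the transcription factor AP-1 (chromosome 12, 85473890 to 85477273), was at 34.0, 49.5, 17.3 and 26.5 CPM, Fosb had a log2 fold change of -0.50 ± 0.23, Klf6 of -0.36 ± 0.21 (-0.14 without Yoda1 1), and Atf3 lay under 0.5 CPM in every library. Cholesterol synthesis genes were higher in 17 of 19 members, with medians of 0.12, -0.13, 0.21 and 0.15. Of these, 9 lay above both controls in both Yoda1 libraries (chance 16.7% for a single gene). The members were not independent, with an estimated correlation of 0.43. Idi1, an isomerase of the pathway, was at 15.2, 12.7, 18.8 and 20.6 CPM, and Insig1, which holds back the pathway's transcription factors, the oxidase Msmo1 and the demethylase Cyp51 had log2 fold changes of 0.54 ± 0.21, 0.40 ± 0.18 and 0.39 ± 0.19.

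**Figure D1:**
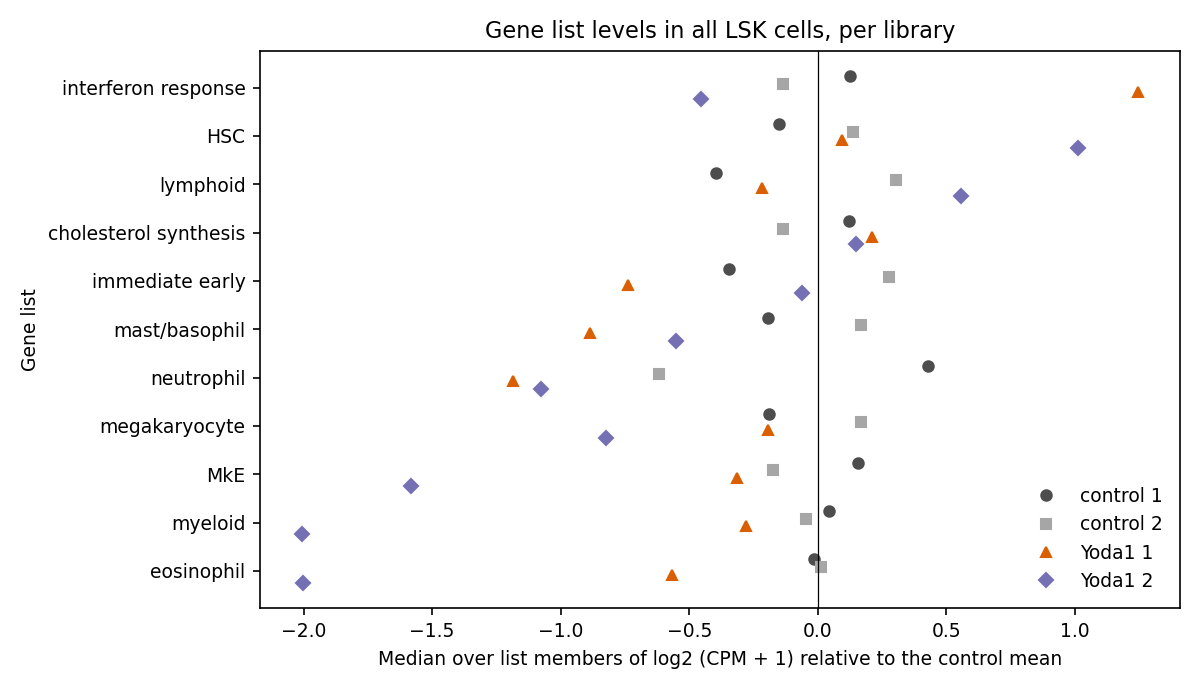
Median level of 11 gene lists in all LSK cells of each library (horizontal axis, log2 of CPM + 1 relative to the control mean, median over list members), 1 marker per library. The interferon list stands at 1.25 in Yoda1 1 and -0.45 in Yoda1 2, the HSC list at 0.09 and 1.01, and the neutrophil list at -1.18 and -1.08.

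Of 36 lists, camera with a preset inter-gene correlation of 0.01 called 18, 3 higher and 15 lower, and 0 of them held with an estimated correlation, where the smallest adjusted p was 0.579, or with fry, where it was 0.819. Of the called lists, 7 kept their call and direction whichever library was left out: myeloid (adjusted p = 4.26e-11), mast cell and basophil (3.38e-10), MkE, neutrophil and myelopoiesis (9.22e-10 each), eosinophil (4.42e-09) and megakaryocyte (5.53e-06). Each of these 7 had an adjusted p of 0.579 with an estimated correlation.

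For the other 11 called lists the call rested on a library. The HSC list (higher, adjusted p = 2.02e-05, and 0.579 with an estimated correlation) was at 0.0985 without Yoda1 2. The interferon list (higher, 3.14e-05, and an adjusted p of 0.669 with an estimated correlation) turned lower without Yoda1 1 (3.63e-07). Cholesterol synthesis (higher, 6.84e-07, estimated 0.579) was at 0.310 without control 2 and 0.0842 without Yoda1 1. Immediate early genes (lower, 2.76e-06, estimated 0.616) were at 0.332 without control 2 and turned higher without Yoda1 1 (0.674). MHC class II (lower, 0.000148, estimated 0.600) was at 0.674 without Yoda1 1. Erythroid genes (lower, 0.00277, estimated 0.600) turned higher without Yoda1 1 (0.474), monocyte genes (lower, 0.00342, estimated 0.579) turned higher without Yoda1 2 (0.0697), and B cell genes (lower, 0.00385, estimated 0.669) were at 0.655 without control 2 and turned higher without Yoda1 1 (0.000693). The unfolded protein response (lower, 0.00566, estimated 0.600) was at 0.169 without control 1 and turned higher without Yoda1 2 (0.524), endothelial genes (lower, 0.0121, estimated 0.579) were at 0.138 without control 2 and 0.474 without Yoda1 1, and oxidative phosphorylation (lower, 0.0257, estimated 0.823) turned higher without control 1 (0.960) and without Yoda1 2 (5.57e-05). With the replicate number as a block, endothelial genes were at 0.0536.

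The remaining lists were not called by camera. Adjusted p was 0.0753 for each of G2/M phase, mechanosensitive channels, and adhesion and cytoskeleton, 0.112 for stromal markers, 0.170 for each of dendritic markers and glycolysis and hypoxia, 0.241 for ribosomal proteins, 0.263 for lymphoid markers, 0.272 for each of quiescence, heat shock and p53 targets, 0.528 for calcium signalling, 0.548 for S phase, 0.550 for T, NK and innate lymphoid markers, 0.837 for YAP/TAZ targets, 0.896 for sex genes, 0.9503 for mitochondrially encoded genes, and 0.956 for NF-kB and inflammatory genes. The T, NK and innate lymphoid list had a median log2 fold change of 0.32 and a lower test direction, and calcium signalling had a median of 0.03, a mean of -0.02 and a higher test direction. With the replicate number as a block G2/M passed as lower (0.0258). Of these lists, 11 passed when a library was left out: lymphoid (higher, 3.70e-05), glycolysis and hypoxia (lower, 0.00236), ribosomal proteins (lower, 0.0237) and G2/M (lower, 4.79e-07) without Yoda1 1, dendritic (lower, 2.34e-11), T, NK and innate lymphoid (lower, 2.25e-06), S phase (higher, 0.000506), quiescence (lower, 0.000822), NF-kB (lower, 0.0321) and mechanosensitive channels (lower, 0.0444) without Yoda1 2, and heat shock (higher, 0.00187) without control 1. For several of them the direction turned with the library, for example for lymphoid markers (lower, 0.000706, without Yoda1 2) and S phase (lower, 0.00136, without Yoda1 1).

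Piezo1, the target of Yoda1 (chromosome 8, 122481698 to 122551329), was at 26.4, 17.5, 21.4 and 13.3 CPM, a log2 fold change of -0.34 ± 0.30. The mechanosensitive channels Trpv4, Pkd2 and Trpv2 had log2 fold changes of -0.39 ± 0.42, 0.29 ± 0.35 and -0.17 ± 0.21. Of the genes of the sort gate, Kit (chromosome 5, 75574916 to 75656722) was at 104, 127, 112 and 142 CPM, and Ly6a, which encodes Sca-1 (chromosome 15, 74994877 to 74998031), at 119, 95.9, 279 and 104. Ly6a is itself induced by interferon and was higher in Yoda1 1, where the interferon list was higher. Mki67, a proliferation marker, was at 281, 244, 302 and 233 CPM, Mpo, myeloperoxidase, at 3607, 2377, 2467 and 596, and Flt3, a receptor of multipotent and lymphoid progenitors, at 57.9, 82.6, 57.9 and 140. None of these passed the test.

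Clustering gave 30 clusters, named by the marker lists, and the comparison of class shares asked whether the make-up of the LSK fraction differed. HSC-like cells made up 12.7%, 15.2%, 31.7% and 47.9% of the libraries (13.9% ± 1.76 in control and 39.8% ± 11.5 in Yoda1, SD, n = 2, exact two-sided permutation p = 0.333). Myeloid-like cells made up 17.6%, 15.7%, 9.09% and 1.90%, MkE-like cells 28.4%, 22.0%, 21.8% and 6.51%, and mast- and basophil-like cells 3.82%, 4.07%, 1.81% and 1.24%. Lymphoid-like cells made up 12.7%, 22.8%, 5.88% and 34.7%, a difference of 2.56 percentage points that turned to -11.9 without Yoda1 2 and -2.47 without control 1, and was 7.59 without control 2 and 17.0 without Yoda1 1. Eosinophil-like cells were at 0.472%, 0.499%, 0.143% and 0.0308%, monocyte- and macrophage-like cells at 12.9%, 8.89%, 15.5% and 2.99%, erythroid-like at 4.93%, 2.33%, 2.94% and 0.523%, dendritic-like at 1.601%, 1.73%, 0.417% and 1.20%, T, NK and innate lymphoid-like at 0.997%, 1.84%, 0.691% and 1.004%, and B cell-like at 0.223%, 1.71%, 0.0110% and 1.04%. The MkE-like, erythroid-like, monocyte- and macrophage-like and lymphoid-like shares depended on the clustering. The MkE-like groups stayed apart only in the main clustering and with doublets removed. At resolution 1.5 the MkE-like shares were 33.0%, 23.9%, 24.1% and 6.86%. Without Yoda1 2 the MkE-like difference of -11.0 percentage points was -3.42. At resolution 1.5 the erythroid-like shares were 0.197%, 0.128%, 0.252% and 0.195%, with values centred per library the monocyte- and macrophage-like shares were 1.56%, 1.34%, 1.06% and 2.07%, and the lymphoid-like shares were 11.4%, 19.7%, 25.8% and 31.8% at resolution 1.5 and 11.7%, 16.6%, 19.9% and 31.2% when centred, in both clusterings above both controls in both Yoda1 libraries. Counting error was small beside the differences between libraries: the exact 95% binomial interval of the HSC-like share ran from 11.95% to 13.5% in control 1 and from 46.9% to 48.9% in Yoda1 2. With 2 libraries per group the smallest permutation p is 0.333, so no share could pass 0.05, and edgeR on cells per class gave a smallest adjusted p of 0.697.

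The HSC-like class was not made of the same clusters in every library. Cluster 2, led by the interferon genes Ifit3, Iigp1 and Ifit1, held 94.98% of the HSC-like cells of Yoda1 1 and 3.73%, 1.68%, 30.1% and 1.10% of all cells of the libraries, while cluster 1 was the largest part of the class in the other 3. Without cluster 2 the HSC-like shares were 8.96%, 13.5%, 1.59% and 46.8%, and the groups overlapped. At resolution 0.5 the interferon-led cluster, then with 41.9% of Yoda1 1, took the name lymphoid-like, and the HSC-like shares were 12.4%, 19.6%, 2.51% and 59.8%. In a clustering without the genes called in Yoda1 1, where 144 variable genes were left out (a setting chosen after the data were seen, as was the removal of cluster 2), they were 8.74%, 11.2%, 14.6% and 44.2%. With values centred per library they were 18.9%, 23.2%, 22.4% and 51.3%, so that the higher share was clear of both controls in Yoda1 2 only. Each library had 1 treatment, so centring also removes average effects of the treatment and cannot tell these from effects of the library. At resolution 1.5, without regression of cell cycle scores, with doublets removed and with the stricter cell filter, both Yoda1 libraries lay above both controls. With values centred, myeloid-like cells were at 21.0%, 18.0%, 20.7% and 2.77%, and the mast- and basophil-like class at 3.91%, 4.26%, 2.06% and 1.30%. In the latter class both Yoda1 libraries lay below both controls in each of the clusterings run. Unnamed clusters held 3.62%, 3.32%, 10.1% and 0.953% of the cells, mostly cluster 10, led by histone genes, with 9.91% of Yoda1 1.

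**Figure D2:**
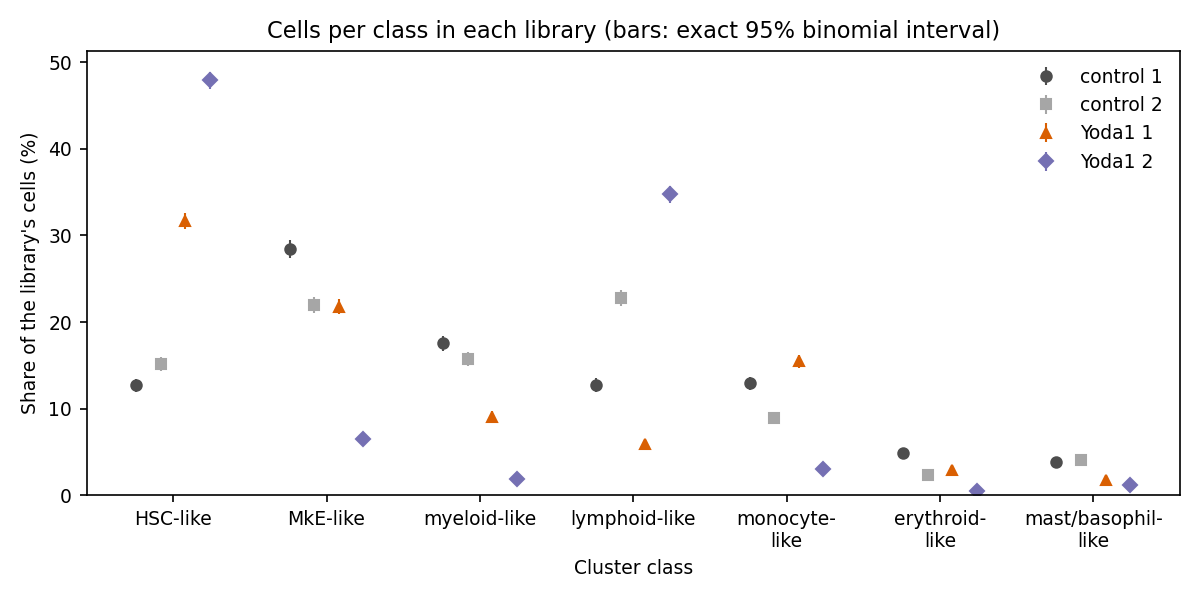
Share of each library's cells in 7 cluster classes (vertical axis, percent), 1 marker per library, with bars for the exact 95% binomial interval. HSC-like cells stand at 12.7% and 15.2% in the controls and 31.7% and 47.9% in the Yoda1 libraries, and mast- and basophil-like cells at 3.82% and 4.07% against 1.81% and 1.24%.

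Within single classes the question was which genes differed, although the mix of clusters in a class still differed between libraries. Fos was the gene with the smallest unadjusted p of those named as lower in HSC-like cells, and was lower in all 4 classes tested. It stood at 65.7, 75.8, 28.7 and 28.0 CPM in HSC-like cells (log2 fold change -1.32 ± 0.13), 23.3, 27.0, 9.43 and 12.7 in MkE-like cells (-1.21 ± 0.19), 19.0, 18.1, 9.19 and 8.44 in myeloid-like cells (-1.05 ± 0.19), and 86.4, 105, 24.99 and 34.95 in lymphoid-like cells (-1.65 ± 0.20). Its log2 fold change in HSC-like cells was -0.83 at resolution 0.5, and in myeloid-like cells -0.59 with values centred per library. In 14 of the 14 clusters with at least 50 cells in each library, Fos lay below both controls in both Yoda1 libraries (chance 16.7%, though clusters of the same library are not independent). In HSC-like cells other immediate early genes were lower too: Klf2, a quiescence-linked transcription factor, had a log2 fold change of -0.97 ± 0.17 and Klf6 of -0.66 ± 0.12. Ccnd1 was higher in HSC-like cells (18.7, 14.1, 34.8 and 31.2 CPM, 1.01 ± 0.17) and in MkE-like cells (0.67 ± 0.14), although in HSC-like cells its log2 fold change was 0.47 with values centred per library.

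edgeR called 0 genes in each class, with 175, 275, 188 and 158 at an unadjusted p under 0.05 of 14368, 14548, 13255 and 13469 tested in HSC-, MkE-, myeloid- and lymphoid-like cells. Each of these counts is a smaller share than the 0.05 that chance alone gives. DESeq2 called 1, 1, 0 and 2: Fos in HSC-like (adjusted p = 8.21e-09), MkE-like (0.0457) and lymphoid-like cells (9.67e-07), and Ccl9, a chemokine, in lymphoid-like cells (log2 fold change in edgeR -1.04 ± 0.15, DESeq2 adjusted p = 0.00679). The adjusted p of Fos in edgeR was 0.309 in HSC-like cells. In MkE-like and lymphoid-like cells the smallest edgeR adjusted p of any gene was 0.9998 and 0.9999. With the replicate number as a block, a numbering that need not pair the libraries, edgeR called 33 genes in myeloid-like cells, among them Fos (adjusted p = 0.000296), Camp (9.45e-13), H2ac4 (2.67e-05) and H2ac8 (0.0007003). Other genes named by the rule, none passing in edgeR without the block, were Il12a (0.72 ± 0.15) and Dntt (0.46 ± 0.12) in HSC-like cells, Slfn9 (0.56 ± 0.14), Hmgn2 (0.61 ± 0.17), Klf6 (-0.82 ± 0.14) and the basophil protease Prss34 (-1.26 ± 0.20) in MkE-like cells, the histone genes H2ac4 (1.08 ± 0.20), H2ac8 (0.75 ± 0.18) and H2bc11 (0.63 ± 0.19), the phosphatase Dusp1 (-0.79 ± 0.22) and Camp (-1.94 ± 0.52) in myeloid-like cells, and Ighv1-77 (1.25 ± 0.30), Idi1 (0.74 ± 0.21), Gimap7 (0.86 ± 0.25) and Cpa3 (-1.51 ± 0.26) in lymphoid-like cells. The histone and immunoglobulin genes have near-identical copies, so their values are uncertain. Free RNA from other cells was not tested for Prss34 in MkE-like or Cpa3 in lymphoid-like cells, which are markers of mast cells and basophils. Several of these were much smaller under an alternative: Il12a 0.16 with values centred per library, Ighv1-77 0.34 and Gimap7 0.20 at resolution 1.5, and H2ac8 0.39 without Yoda1 1. Camp in myeloid-like cells was at 30.1, 6.71, 4.15 and 6.33 CPM, with a log2 fold change of -0.45 without control 1. Dntt in HSC-like cells at resolution 0.5, and Ccl9 and Cpa3 in lymphoid-like cells at resolution 1.5, changed sign. Left-out libraries changed the counts: without Yoda1 1, edgeR called 50, 126, 52 and 103 genes in the 4 classes, without Yoda1 2 125, 60, 70 and 191, and without control 2 0, 0, 19 and 0. The lymphoid-like class was mostly cluster 11 in Yoda1 1 (77.1%) and mostly cluster 0 in the other libraries.

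**Figure D3:**
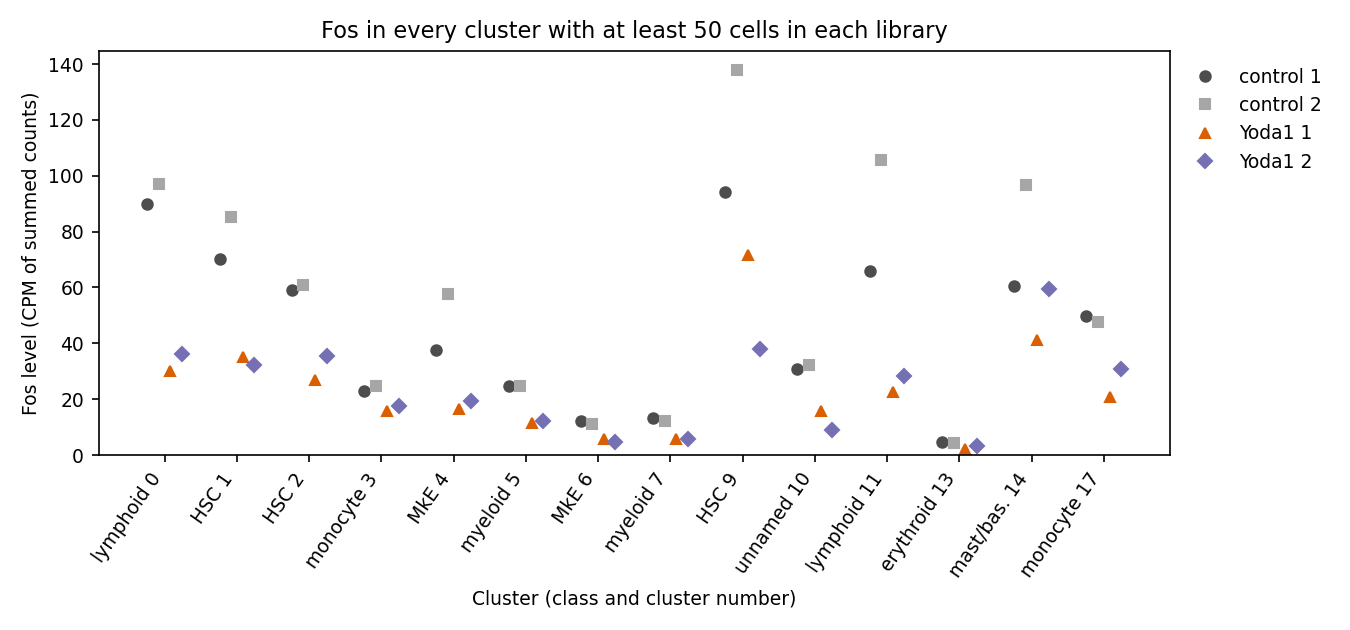
Fos level (vertical axis, CPM of summed counts) in each of the 14 clusters with at least 50 cells in every library, 1 marker per library. In all 14 both Yoda1 libraries lie below both controls, for example at 35.2 and 32.2 against 70.2 and 85.3 CPM in HSC-like cluster 1.

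Gene lists in HSC-like cells asked what moved in the stem cell class. All 15 measured immediate early genes were lower, with medians of -0.27, 0.23, -0.59 and -0.60, and 5 fell adjusted over the list alone (Fos, Klf2, Klf6, Fosb and Dusp1), against 0 over all genes. Of 19 cholesterol synthesis genes 18 were higher, with medians of 0.09, -0.09, 0.31 and 0.25. Of these, 12 lay above both controls in both Yoda1 libraries (chance 16.7% for a single gene). The members were not independent here either, with an estimated correlation of 0.25. All 54 G2/M genes were lower, 20 of them below both controls in both Yoda1 libraries, with medians of 0.04, -0.04, -0.38 and -0.06. The interferon list stood at 0.20, -0.23, 1.42 and -1.15, and the HSC list at -0.03, 0.03, -0.18 and 0.30. Adjusted over the list alone, the 2 measured neutrophil genes fell (S100a8, S100a9), which were too few for a list test, and 1 gene of the dendritic list, Cox6a2, rose (1.34 ± 0.37). The neutrophil medians in HSC-like cells were 0.38, -0.55, -1.06 and -0.75, in the same order as the 0.43, -0.62, -1.18 and -1.08 over all cells. Free RNA from other cells was not tested for these genes, so a fall inside HSC-like cells is not shown.

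Camera with the preset correlation called 11 of 33 lists in HSC-like cells, and 0 held with an estimated correlation (smallest adjusted p = 0.670) or with fry (0.465). The immediate early list (lower, adjusted p = 3.61e-16) and cholesterol synthesis (higher, 3.79e-12) kept their calls whichever library was left out, each with an adjusted p of 0.670 with an estimated correlation. G2/M phase (lower, 7.14e-17, estimated 0.670) was at 0.05002 without Yoda1 1. Lower lists that rested on Yoda1 2, each with an estimated adjusted p of 0.670, were MkE (2.68e-07, and 0.306 without Yoda1 2), mast cell and basophil (0.000182, and 0.775), myeloid (0.000182, and higher at 0.00753), myelopoiesis (0.000729, and higher at 0.148) and monocyte (0.0185, and higher at 0.0209). Without control 1 the myeloid list was at 0.0881 and the monocyte list at 0.799. The higher lists heat shock (0.00213, estimated 0.670), oxidative phosphorylation (0.00261, estimated 0.752) and ribosomal proteins (0.0427, estimated 0.670) were at 0.434, 0.659 and 0.383 without control 2, and the latter pair at 0.983 and 0.831 without Yoda1 1. Of the lists not called, interferon genes turned from higher (2.36e-61 without Yoda1 2) to lower (9.51e-48 without Yoda1 1), and HSC genes from lower (0.0157) to higher (1.23e-05). With the replicate number as a block, a setting chosen after the data were seen, 13 lists were called: monocyte genes were no longer called (0.0937), while interferon (higher, 0.000663), B cell (lower, 0.004996) and dendritic genes (higher, 0.0475) were. The number of lists called was 10 without control 2 and 17 without Yoda1 2. The HSC-like class of Yoda1 1 was mostly the interferon-led cluster 2. For the lower lineage lists free RNA from other cells was not tested, so a change inside HSC-like cells is not shown for them.

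Whether the response of HSC-like cells differed from that of another class was tested as an interaction. edgeR called 0 genes against MkE-like (15587 tested), 0 against myeloid-like (14852) and 0 against lymphoid-like cells (14340), with 750, 519 and 170 at an unadjusted p under 0.05. None of these counts exceeds the share of 0.05 that chance alone gives. No other tool was run on the interaction. Without Yoda1 1 the counts were 343, 58 and 75, without Yoda1 2 273, 120 and 765, and without control 2 0, 8 and 0.

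The series title names proliferation, and the share of cells scored in S or G2/M was compared after each cell was thinned to 3000 UMIs. Over all LSK cells it was 81.2%, 67.9%, 78.9% and 58.5%, and in HSC-like cells 62.9%, 51.2%, 53.5% and 58.9% (57.1% ± 8.25 in control and 56.2% ± 3.84 in Yoda1, SD, n = 2, exact permutation p = 1). In HSC-like cells the G2/M share alone was 28.8%, 26.5%, 23.4% and 26.2%, below both controls in both Yoda1 libraries (exact permutation p = 0.333), with a difference from -1.43 points without Yoda1 1 to -4.28 without Yoda1 2. The S share alone was 34.1%, 24.8%, 30.1% and 32.7% (exact permutation p = 1), and its difference of 1.96 points turned to -2.71 without control 2. The pooled difference in HSC-like cells lay within the spread between libraries and changed sign with the library left out, from -6.73 percentage points without control 2 to 4.94 without control 1, with 1.83 without Yoda1 1. Over all cells the difference of -5.86 points ran from -16.1 without Yoda1 1 to 4.35 without Yoda1 2, with 0.775 without control 1. MkE-like cells were at 85.4%, 78.1%, 88.3% and 87.3%, myeloid-like cells at 90.8%, 85.3%, 93.1% and 90.8%, and lymphoid-like cells at 58.8%, 45.9%, 68.6% and 46.3%, where the difference of 5.08 points turned to -6.07 without Yoda1 1 and -1.37 without control 2, and was 16.2 without Yoda1 2 and 11.5 without control 1. In MkE-like cells both Yoda1 libraries lay above both controls, by 6.04 points (2.43 without control 2, 9.64 without control 1). The myeloid-like G2/M share alone was 50.85%, 44.1%, 53.9% and 56.0%, above both controls in both Yoda1 libraries (exact permutation p = 0.333). The myeloid-like S share alone was 40.0%, 41.3%, 39.3% and 34.8%, below both controls in both. Without thinning the shares were 79.8%, 65.5%, 78.0% and 54.0% over all cells and 59.5%, 48.6%, 51.1% and 54.5% in HSC-like cells. Phase calls read RNA, free RNA included, and measure no division.

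Heterogeneity, also named in the title, was lower in both Yoda1 libraries by both measures. The Shannon entropy of the cluster shares was 2.88, 2.93, 2.37 and 2.33 nats (2.91 ± 0.0367 in control and 2.35 ± 0.0275 in Yoda1, SD, n = 2, exact permutation p = 0.333, the smallest this design can give). The mean squared distance of thinned cells to their library's centroid in principal component space was 143, 180, 122 and 110 (162 ± 26.1 and 116 ± 9.06, exact permutation p = 0.333). Without thinning the distances were 241, 304, 197 and 180. Without control 2 the difference in distance was -27.2, and without control 1 -64.2. The 2 Yoda1 libraries were filled by different clusters: cluster 2 held 94.98% of the HSC-like cells of Yoda1 1, and cluster 1 held 47.7% of those of Yoda1 2. Entropy was recomputed only at other resolutions, not with values centred per library or without the genes called in Yoda1 1. Lower entropy in both therefore need not be a shared change.

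**Figure D4:**
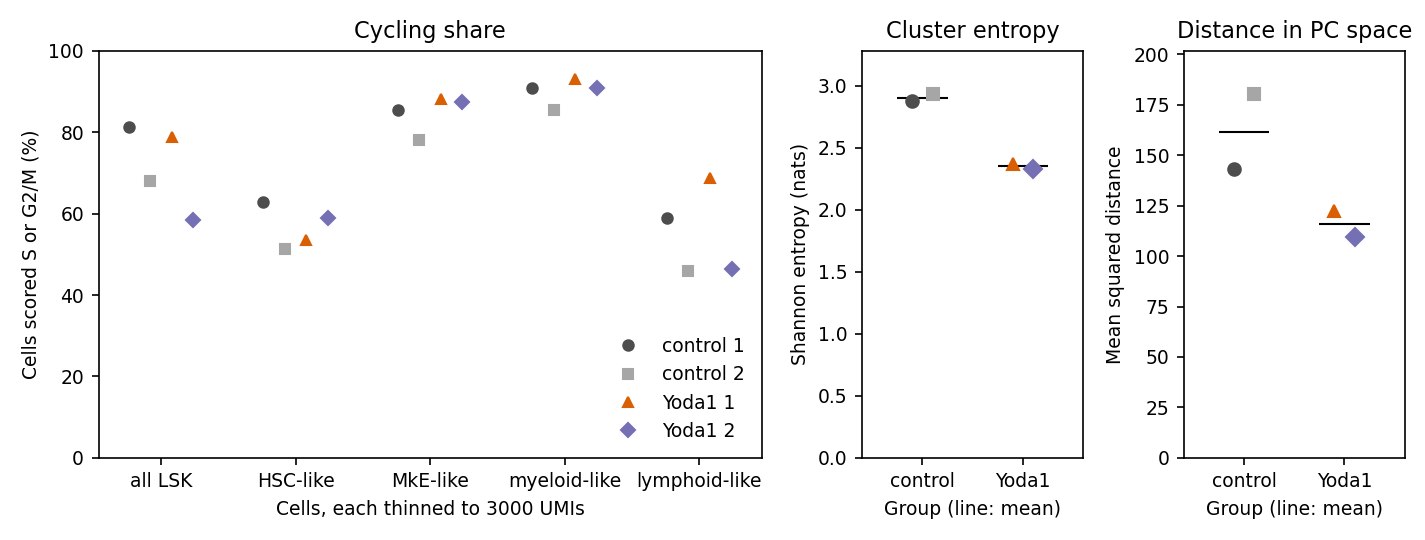
Left, share of cells scored in S or G2/M (percent) in all LSK cells and 4 classes after thinning to 3000 UMIs per cell; middle, Shannon entropy of cluster shares (nats); right, mean squared distance to the library centroid, with 1 marker per library and a line at each group mean. Entropy stands at 2.88 and 2.93 in the controls and 2.37 and 2.33 in the Yoda1 libraries, while the cycling share of HSC-like cells overlaps between groups.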

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

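Several alternatives were chosen after the data were seen: class tests centred per library, the HSC-like class without its interferon-led cluster, clustering without the genes called in Yoda1 1, and fry and the replicate block for lists in HSC-like cells. The planned clustering without genes called over all cells was not run, since 0 were called. Of 81 results for named genes, 69 kept their sign in every alternative and 12 did not; with members of all 36 lists named, 132 of 170 would have and 38 would not. Counts of calls stayed at 0 over all cells with RLE, voom, no filter, the strict filter, every barcode and doublets removed. Depth differed between the 4 classes tested: summed UMIs ran from 3302922 in myeloid-like to 42427408 in HSC-like cells, both of Yoda1 2. Where a value below differs from the text, the cause was not tested, except that leaving out a library leaves fewer samples.

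Gene counts at an adjusted p of 0.05, all 0 in edgeR, were 4 with DESeq2 over all cells, 1 in HSC-like, 1 in MkE-like and 2 in lymphoid-like cells with DESeq2, and 66, 115, 36 and 62 in HSC-, MkE-, myeloid- and lymphoid-like cells with no filter on low counts. The replicate number as a block, which rests on a numbering that need not pair the libraries, gave 1 in MkE-like cells, Igkc, and 33 in myeloid-like cells, among them Fos, Camp, H2ac4 and H2ac8, and the HSC-like class without the interferon-led cluster gave 1, Ccl9 (edgeR adjusted p = 0.0362). With a library left out the counts ran from 0 to 938 over all cells, 0 to 125 in HSC-like, 0 to 126 in MkE-like, 0 to 70 in myeloid-like and 0 to 191 in lymphoid-like cells, and the interactions from 0 to 343 (MkE-like), 0 to 120 (myeloid-like) and 0 to 765 (lymphoid-like). With an estimated correlation or fry 0 lists were called over all cells and 0 in HSC-like cells, and the HSC-like count ran from 10 to 17 with a library left out.

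The HSC-like share difference, 25.8 percentage points, was 12.96 without the interferon-led cluster, 15.2 at resolution 0.5, 16.5 at resolution 1.5 and 15.8 with values centred per library. The myeloid-like difference was -6.58 at resolution 1.5, and the lymphoid-like difference, 2.56, was 12.5 at resolution 0.5, 13.3 at resolution 1.5, 11.4 centred per library, 10.57 without regression of cell cycle scores, 8.41 with doublets removed, 8.63 with the stricter cell filter and 7.49 without the genes called in Yoda1 1, and ran from -11.9 to 17.0 with a library left out. The erythroid-like difference, -1.90, lay between -0.0461 (stricter cell filter) and 0.0781 (doublets removed) in every other clustering. The monocyte- and macrophage-like difference, -1.67, was 0.115 when centred and at resolution 0.5, 1.38 with the stricter cell filter, and between -1.903 and -0.177 in the others. The cycling difference of HSC-like cells was 1.45 without the interferon-led cluster and ran from -6.73 to 4.94 with a library left out; the S share alone ran from -2.71 to 6.64, with 8.16 without the interferon-led cluster, and the G2/M share alone from -4.28 to -1.43, with -6.71 without that cluster and -2.79 with the stricter cell filter, where the groups overlapped. Over all cells the cycling difference ran from -16.1 to 4.35 and in lymphoid-like cells from -6.07 to 16.2. The entropy difference was -0.677 at resolution 0.5 and the distance difference -83.97 without thinning. Dntt in HSC-like cells had a log2 fold change of -0.14 at resolution 0.5, and Ccl9 and Cpa3 in lymphoid-like cells 0.0142 and 0.55 at resolution 1.5. With a library left out the log2 fold changes over all cells ran from -0.0406 to 0.29 for Kit, -0.0618 to 1.38 for Ly6a, -0.18 to 0.21 for Mki67, -0.28 to 0.99 for Flt3, -4.54 to 0.98 for Pax5, -3.95 to 1.46 for Ebf1, -6.93 to 1.27 for Vpreb3, -2.69 to 1.08 for Vpreb1 and -0.25 to 0.68 for Pkd2. Without a change of sign they ran from -3.88 to -1.92 for Ngp, -3.28 to -1.36 for Camp, -1.53 to -0.49 for Gfi1b, -1.04 to -0.32 for Itga2b, -2.19 to -0.46 for Mfsd2b and -2.46 to -0.49 for Aqp1, and for Camp in myeloid-like cells from -2.65 to -0.45. Over all alternatives, other log2 fold changes that moved by over 1.5 times without a change of sign ran, over all cells, from 0.43 to 0.98 for Ifi203, 0.50 to 1.21 for Il18, -1.87 to -0.81 for S100a8, -2.44 to -1.05 for Hdc, -0.74 to -0.0181 for Piezo1, 0.22 to 2.27 for Procr, -2.34 to -0.28 for Mpo, 0.25 to 1.74 for Mecom, 0.15 to 1.83 for Hlf, -2.65 to -0.98 for Cebpe, -1.98 to -0.52 for Fcgr3, -2.40 to -0.54 for Elane, -1.80 to -0.70 for S100a9, -1.25 to -0.42 for Fcer1a, -3.88 to -0.89 for Prg2, -2.84 to -0.82 for Ear6, -1.66 to -0.79 for Ear1, 0.0673 to 2.98 for Ifit3, 0.0312 to 2.06 for Iigp1, -0.67 to -0.32 for Fosb, -0.62 to -0.14 for Klf6, -0.30 to -0.0387 for Trpv2, -1.23 to -0.11 for H2-Ab1, -2.09 to -0.18 for H2-Aa and -2.16 to -0.0851 for Cd74. These ran, in HSC-like cells, from 0.47 to 1.23 for Ccnd1, 0.16 to 0.86 for Il12a, -1.41 to -0.83 for Fos and -0.73 to -0.39 for Klf6. These ran, in MkE-like cells, from 0.41 to 0.86 for Hmgn2. These ran, in myeloid-like cells, from 0.69 to 1.34 for H2ac4, 0.39 to 1.02 for H2ac8, -1.26 to -0.59 for Fos and -0.95 to -0.52 for Dusp1. These ran, in lymphoid-like cells, from 0.34 to 1.57 for Ighv1-77 and 0.20 to 1.13 for Gimap7.

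Camera's adjusted p of lists over all cells ran, with a library left out, from 3.70e-05 to 0.0354 for lymphoid, 5.51e-08 to 0.0697 for monocyte and macrophage, 2.34e-11 to 0.883 for dendritic, 2.51e-37 to 0.655 for B cell, 2.25e-06 to 0.248 for T, NK and innate lymphoid, and 6.65e-23 to 0.474 for erythroid markers. The ranges were 0.000506 to 0.0789 for S phase, 4.79e-07 to 0.262 for G2/M phase, 0.000822 to 0.544 for quiescence, 0.351 to 0.976 for calcium signalling, 0.593 to 0.9903 for YAP/TAZ targets, 1.14e-36 to 0.674 for immediate early genes, 0.00187 to 0.847 for heat shock, 4.48e-140 to 0.0166 for interferon response and 0.0321 to 0.304 for NF-kB and inflammatory genes. They were 5.17e-09 to 0.960 for oxidative phosphorylation, 0.0697 to 0.602 for mitochondrially encoded genes, 0.00236 to 0.987 for glycolysis and hypoxia, 0.0237 to 0.918 for ribosomal proteins, 5.61e-05 to 0.524 for the unfolded protein response and 0.142 to 0.602 for sex genes. Each of these 21 lists turned direction for at least 1 library left out.

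In HSC-like cells camera's adjusted p ran from 1.23e-05 to 0.829 for HSC, 2.25e-29 to 0.0881 for myeloid, 2.78e-09 to 0.799 for monocyte and macrophage, 0.00958 to 0.974 for B cell, 0.0429 to 0.862 for T, NK and innate lymphoid, and 0.0679 to 0.659 for erythroid markers. Process lists ran from 2.16e-05 to 0.0715 for S phase, 0.0157 to 0.908 for quiescence, 6.40e-18 to 0.148 for myelopoiesis, 0.1104 to 0.997 for calcium signalling, 2.36e-61 to 0.886 for interferon response, 0.236 to 0.907 for NF-kB and inflammatory genes, 0.0349 to 0.775 for mitochondrially encoded genes and 0.00275 to 0.974 for glycolysis and hypoxia. The others ran from 0.02305 to 0.932 for the unfolded protein response, 0.356 to 0.859 for p53 targets, 0.1202 to 0.493 for adhesion and cytoskeleton, 0.000303 to 0.803 for MHC class II and 0.04499 to 0.974 for sex genes. Each of these 19 lists, too, turned direction for at least 1 library left out.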

Other observations

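The tests in this part were chosen after the results they bear on had been seen. The treatment is the only factor that the labels give. They do not say whether the libraries came from separate mice and name no batch, so differences between mice or batches stay open throughout. All 20 interferon genes lay above both controls in Yoda1 1, against 3 in Yoda1 2. The lowest list median of Yoda1 1 among the 4 main classes was 1.14 on the log2 scale, in MkE-like cells. Free RNA adds a like number of UMIs to each droplet, so a change larger than the whole content of cells at least as deep cannot come from it alone. Relative to such a content the added UMIs of the list were at least 1.21 in lymphoid-like cells, which argues against free RNA as the whole cause there, but 0.9155, 0.472 and 0.5204 in HSC-, MkE- and myeloid-like cells, where free RNA, and a single cell type as its origin, stay open.

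Stem cell genes were high and lineage genes low in Yoda1 2. The class shares went the same way, with 47.9% HSC-like, 6.51% MkE-like and 1.90% myeloid-like cells in that library. Within HSC-like cells its HSC, MkE and myeloid list medians were 0.30, -0.80 and -1.43, smaller than the 1.01, -1.58 and -2.01 over all cells. Much of the pattern over all cells thus went with the mix of cells. The classes were named by the same markers, so these readings are not independent. At equal depth the MkE list of Yoda1 2 stood at -1.61 on the log2 scale against the lower control, beyond the difference between the controls. This argues against the weight of deep cells in the summed counts as the cause. Thinning keeps each cell's proportions on average, so the test could not show any other effect of depth. A sort gate set differently stays open: Ly6a, the gene of the Sca-1 gate, was at 103.5 CPM in Yoda1 2, within the 95.9 to 119 CPM of the controls, but transcript level need not follow the surface protein that the gate reads.

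Fos was lower in both Yoda1 libraries in 4 classes. The share of clusters with both Yoda1 libraries below both controls was 100%, which argues against another mix of clusters as the cause. The smallest fall between a control and a Yoda1 library was 0.276 UMIs per cell in HSC-like and 0.425 in lymphoid-like cells, 1.61 and 2.47 times the most Fos that erythroid-like control cells, which are deeper, held (0.172, upper 95% limit), which argues against free RNA as the whole cause there; in MkE-like and myeloid-like cells the ratios were 0.881 and 0.793 and free RNA stays open. Immediate early genes may also differ with handling or dissociation of the cells; the lower heat shock median of the 2 Yoda1 libraries in HSC-like cells was 0.0621, which left this open.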
